A study of Homo sapiens with 3 samples.

How the data were processed

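RNA of the human cholangiocarcinoma cell line RBE was measured on 3 single-colour (Cy3) Agilent microarrays: cells before elemene (0 h), after 24 h and after 48 h. The labels give 1 array for each time. Sample titles and source names number the replicates differently, and the series' design text speaks of repeated experiments with donors, which does not match 1 established line on 3 arrays. The arrays were therefore treated as single samples without replicates. Per the labels' protocols, cells were grown with 5% fetal bovine serum and treated in medium with 10%. No vehicle array at 24 h or 48 h was analysed here, so time in culture and serum change together with elemene. The arrays come from 1 slide scan, so no comparison crosses slides or scans.

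Per the file headers, spot intensity was extracted with Agilent Feature Extraction 10.7.1.1, the version that the submitters' processing notes also name. The deposited intensity (the processed signal) is background-subtracted and spatially detrended within each array and was not normalised between arrays. The files flag spots well above background, saturated spots and outlier spots. The deposited series table holds log2 values with the same quantiles in each column, with a median of 3.35 in all 3 columns. Each column follows the processed signal of its own array, with a Spearman correlation of 1.00 over probes. How the authors made that table is not given in the sources used here, so its values served as an alternative.

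Each array has 62976 spots, of which 60901 are not controls and belong to 58201 probes. Outlier-flagged spots were left out (175, 136 and 200 at 0 h, 24 h and 48 h), and log2 signals of spots of one probe were averaged. No spot was saturated. From log2 of the processed signal the array's 75th percentile over all probes was subtracted. Spots were named through their RefSeq accession and a RefSeq gene table (assembly GRCh38.p14, used for names only). Of 33075 probes with such an accession, 31099 matched and gave 22436 symbols. The 27093 probes without a symbol entered the scaling and no gene count. Y-linked genes and the X-inactivation transcripts XIST and TSIX were left out (94 probes). No genome build is named for the probes, so no coordinates are given.

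A gene was represented by its brightest probe and entered a comparison if that probe was well above background on at least 1 of the arrays compared. For a probe not well above background on 1 of them, the dim side was set to the higher of its own level and the lowest level among probes well above background on that array. Its change was set to 0 where this left none. Such changes are called lower bounds here. Where the dim side kept its own level, the value is a ratio to an undetected signal and not a strict bound, so "at least N-fold" is not used for it. A gene counted as changed at a log2 change of at least 1 (2-fold). With 1 array per time there is no replicate check, no test and no p-value. The number of arrays limits the precision. A technical scale comes from the probes with 10 spots: the median SD of log2 signal over the 10 spots was 0.0913 at 0 h, 0.0468 at 24 h and 0.0426 at 48 h, over 280, 280 and 281 probes. A second comes from genes with a further measured probe: the robust SD per probe of the log2 change was 0.19, 0.24 and 0.24 for 24 h against 0 h, 48 h against 0 h and 48 h against 24 h. Neither covers differences between cultures. Among changed genes with another measured probe, all probes moved the same way in 38 of 56, 60 of 84 and 157 of 177 genes, in the same order.

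Before the data were examined, 44 gene lists were fixed. For each list with at least 5 measured members, the median log2 change was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart below the 2.5 or above the 97.5 percentile. The percentile describes these arrays and is not a p-value, because genes of a list are not independent.

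The rule for named genes, also fixed beforehand, took the 12 largest differences in each direction against 0 h and the 5 largest for 48 h against 24 h. It required a brightest probe well above background on all 3 arrays, further measured probes moving the same way, and a name that is not an uncharacterised locus, long intergenic or antisense name. It added the 3 largest lower bounds in each direction and up to 4 members of each list. Most of the largest increases against 0 h turned out to lie in patches of neighbouring spots that deviate together on 1 array. A spot was placed in a patch if the median deviation of at least 8 neighbours well above background on some array in a window of 7 by 7 spots exceeded 0.5 (log2), or if at least 3 neighbours in a window of 5 by 5 deviated by over 2 (log2) the same way. The main values keep these spots. Genes named because they lie outside patches, and other genes that the rule does not take, were chosen after their values were seen.

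Overlap and correlation of the changes at 24 h and 48 h share the 0 h array, which cannot be split. They were set beside independent lists and beside 100 simulations of unchanged arrays with 1 shared control, whose noise was drawn from the differences between the 48 h and 24 h arrays, divided by the square root of 2, within expression bins. That noise contains real differences between these arrays and gave longer lists of changed genes than the data did. The simulation gives all 3 arrays the same noise, which sets its correlation near 0.50 in advance. The error of the 0 h array, whose SD over 10 spots was larger, is not known.

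Alternatives fixed beforehand were scaling to the median of probes well above background on all arrays, quantile normalisation, normexp background correction (offset 50; limma 3.58.1 in R 4.3.3), the series table's values, a filter requiring both arrays, no filter, the mean of a gene's probes, thresholds of log2 2 and of 1.5-fold, and random lists not matched on expression. Alternatives added after seeing the data were leaving out spots in patches and scaling to the 75th percentile of probes well above background on all arrays. The second was added because most probes were not well above background (those that were made up 40.6%, 44.2% and 42.9%). The calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

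The gene counts and list percentiles were tested on simulated data for 24 h against 0 h with 13570 genes, a noise SD of 0.2 per array and 200 genes made to change. Of 50 genes each made to change by log2 -2.0, -1.5, 1.5 and 2.0, the counts recovered 50, 47, 49 and 50, and 3 unchanged genes were counted as changed. Of 200 lists of unchanged genes, 12 stood apart. Of 20 lists shifted by 0.4, all 20 stood apart. All simulated genes were well above background, with independent noise and without patches. Lower bounds, patches and dependence among genes of a list were therefore not tested.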

Results

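The data describe how transcript levels in RBE, an established human cholangiocarcinoma (bile duct cancer) cell line, differed before and after exposure to elemene, a plant-derived sesquiterpene preparation. There was 1 array for untreated cells at 0 h, 1 for cells after 24 h and 1 for cells after 48 h. Of 60901 spots that are not controls, 26164 were well above background at 0 h, 28276 at 24 h and 27490 at 48 h. The 75th percentile of the signal was 202, 235 and 286. There are no replicates at any time, so none of the differences has a replicate check, and no p-values are given. No array of vehicle-treated cells at 24 h or 48 h was analysed here. All changes below are log2 differences between 2 arrays after scaling. List medians are read against random lists of equal expression, because the median of all genes was itself -0.10 at 24 h and 0.03 at 48 h against 0 h.

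**Figure D1:**
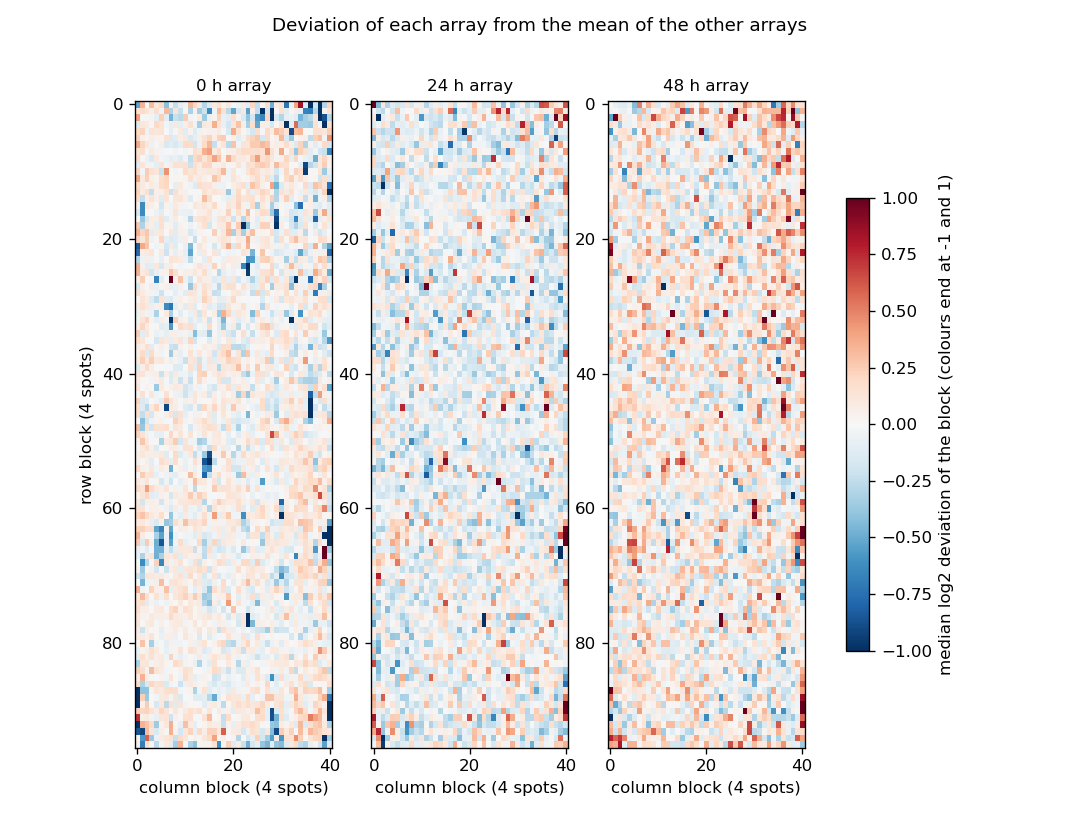
Position of spots on the 0 h, 24 h and 48 h arrays in blocks of 4 by 4 spots; colour gives the median log2 deviation of a block from the mean of the other arrays, for spots well above background on some array. Blocks of strong colour at the edges and in small clusters are the patches, which hold 1194, 919 and 1457 spots.

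The first comparison asks which transcripts differed after 24 h of elemene. Cell-cycle genes were lower as a group. The list of mitosis and G2/M genes had a median log2 change of -0.86 over 64 measured genes, at percentile 0 of random lists, whose central 95% ran from -0.23 to -0.06. Of its genes, 22 were lower by at least 1 and 0 were higher. They included the proliferation marker MKI67 (-1.43), the centromeric histone CENPA (-1.37) and the mitotic kinesins KIF20A (-1.35) and KIF23 (-1.32). Genes of DNA replication were lower in median by -0.59 over 47 genes (percentile 0), among them the licensing factor CDT1 (-0.999) and the ribonucleotide reductase subunit RRM2 (-0.82). RPA3, which read 3.10 higher, lies in a patch of neighbouring spots that deviate together on 1 array. Replication-dependent histones had a median of -0.37 over 39 genes (percentile 0), although H3C1 was higher by 1.97. Its paralogs are near-identical and are not separated here. Homologous recombination and Fanconi repair genes had a median of -0.38 over 31 genes (percentile 0.02), with RBBP8, a factor in DNA end resection, at -1.34.

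Growth-related lists were lower too at 24 h. Targets of the Hippo effectors YAP and TEAD had a median of -0.47 over 24 genes (percentile 0). CCN2, a matricellular growth factor, was at -1.31, and the apoptosis inhibitor BIRC5 at -1.07. Ribosome biogenesis and MYC targets had a median of -0.33 over 44 genes (percentile 0.09), including PNO1 (-0.79) and LYAR (-0.74). Mesenchymal markers had a median of -0.36 over 19 genes (percentile 0.2), with the matrix protein TGFBI at -0.60 and, in the other direction, SNAI2 at 0.66. This list no longer stood apart with normexp background correction, with both arrays required above background or with the mean of all probes.

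Some lists of stress, lipid and lysosomal genes stood on the high side at 24 h by small amounts. Others did not stand apart: heat shock genes had a median of -0.13 (percentile 66.9), metallothioneins -0.06 (percentile 86.7), p53 targets -0.12 (percentile 64) and ferroptosis and glutathione genes -0.03 (percentile 97.4). NRF2 targets had a median of 0.11 over 37 genes (percentile 100). The autophagy receptor SQSTM1 was higher by 1.12, the cystine transporter SLC7A11 by 0.89 and heme oxygenase HMOX1 by 0.74. Autophagy and lysosome genes had a median of 0.07 over 41 genes (percentile 100), with MAP1LC3B at 0.73. Cholesterol synthesis genes had a median of 0.17 over 26 genes (percentile 100) and fatty acid synthesis genes 0.09 over 23 (percentile 99.97). STARD4, a sterol transporter, was at 0.60. ACAT2, which read 3.31 higher, lies in a patch. The list of ATF4 and the integrated stress response had a median of 0.00 over 32 genes (percentile 99.93), tRNA synthetases -0.01 over 15 (percentile 99.28) and ribosomal proteins -0.05 over 71 (percentile 99.97). These 3 lists stood above random lists without being higher on the scaled values, and none of them stood apart without matching on expression. The sign of the median depended on the setting for the ATF4 list (-0.03 without the filter), for tRNA synthetases (0.13 after quantile normalisation) and for ribosomal proteins (0.07 with scaling to the 75th percentile of probes well above background on all arrays). The interferon list had a median of 0.10 over 33 genes (percentile 99.22). It included the RNA sensors IFIH1 (1.48) and RIGI (1.13), and IFI44 (1.39). It did not stand apart with the mean of all probes. Markers of cholangiocytes, the bile duct cells, had a median of 0.12 over 18 genes (percentile 99.96). Hepatocyte markers had a median of 0.26 over 10 genes (percentile 98.58) and did not stand apart after quantile normalisation, with normexp, with the series table or without the filter, where their median was -0.30.

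**Figure D2:**
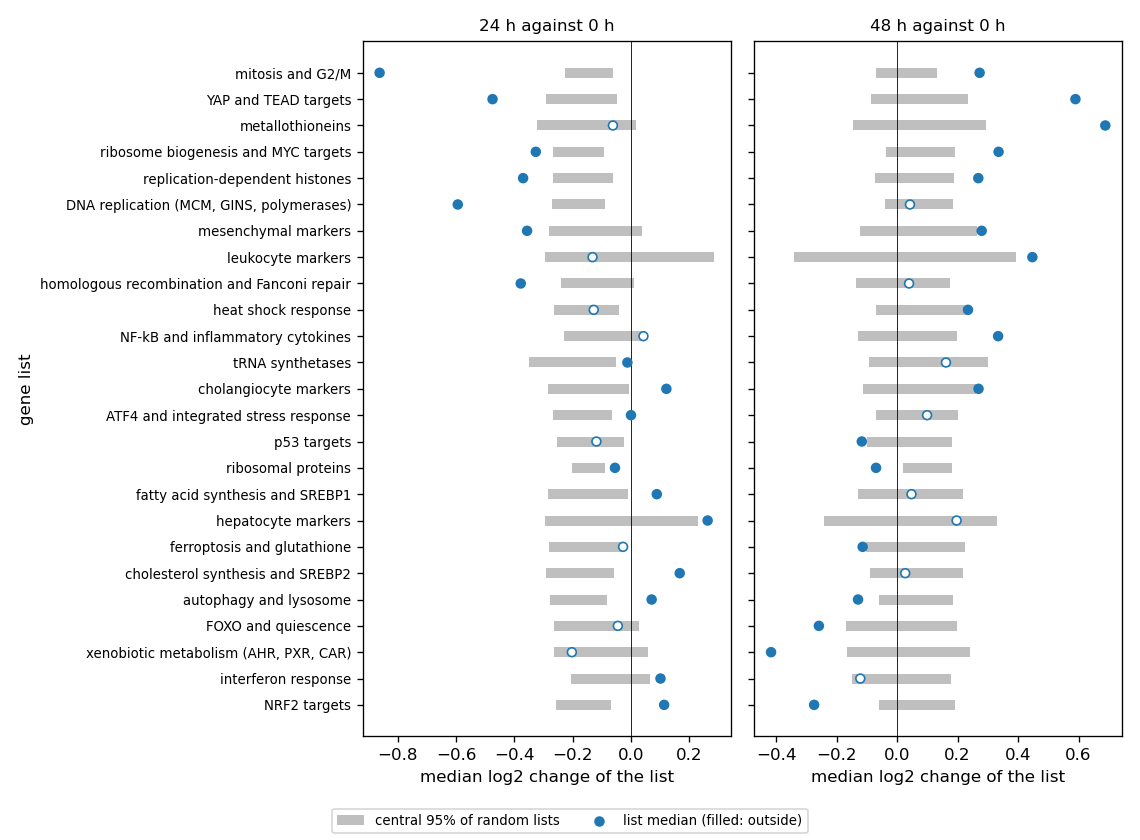
Median log2 change of gene lists (circles) at 24 h (left) and 48 h (right) against 0 h, for lists outside the central 95% of random lists at either time. Grey bars give the central 95% of random lists matched on expression and filled circles lie outside it. The mitosis list lies at -0.86 at 24 h and at 0.27 at 48 h.

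Of 14622 genes compared at 24 h, 227 were higher and 191 lower by at least 2-fold. Of these, 127 rest on a lower bound and 100 lie in patches of spots. Of the 12 largest increases that the rule took, 9 lie in such patches: RHBDL1, GSDMD, ACAT2, DRC10, RPA3, GTF3A, RTF2, ENGASE and CHST1, from 12.6-fold for RHBDL1 to 5.43-fold for CHST1. The others were OLAH, a thioesterase of fatty acid synthesis (5.76-fold), PPP1R2, a phosphatase inhibitor (6.61-fold, while another of its probes gave a log2 change of 0.43), and the pseudogene RPS10P7 (9.22-fold), which is not separated from its parent gene here. Outside patches, further increases were seen for the somatostatin receptor SSTR3 (2.18), the transcription factor ETV1 (1.81, while 3 other probes gave 0.45 to 0.59) and the GDNF receptor GFRA1 (1.76). The ribosomal RNA RNA18SN5 also read higher, by 1.84 at 24 h and 2.03 at 48 h against 0 h. The decreases were less affected, with 2 of 12 (GLUL and PPP1R37) in patches. The immune checkpoint ligand VTCN1 was lower by 3.96-fold. The dynein intermediate chain DYNC1I1 (3.78-fold), the muscle stress protein ANKRD2 (3.76-fold), the ubiquitin ligase components FBXO2 (3.59-fold) and G2E3 (3.57-fold), guanine deaminase GDA (3.43-fold), KIRREL3 (3.39-fold), NEURL1B (3.27-fold), the BMP antagonist NOG (3.22-fold) and ATP6V0A4 (3.18-fold) were lower too. The largest values entered as lower bounds were 14.3-fold higher for STX17-DT, 13.0-fold for PTBP1 and 12.5-fold for PHOSPHO1. These increases are ratios to the probe's own undetected signal at 0 h and not strict bounds. SLC6A13 was at least 18.0-fold lower, ERVW-1 11.5-fold and PABPC4L 9.36-fold. All 6 lie in patches. Scaling to the 75th percentile of probes well above background on all arrays, chosen after seeing the data, gave 73.0% of the changed genes higher instead of 54.3%, and normexp gave 67.8% of 149 genes. At a threshold of 1.5-fold most changed genes were lower instead, with 742 higher and 1026 lower (42.0% higher).

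The second comparison asks the same after 48 h. Here the mitosis list stood on the high side, with a median of 0.27 over 65 genes (percentile 100; random lists -0.07 to 0.13). The anaphase activator CDC20 was higher by 1.04, SGO2 by 0.90, NCAPH by 0.74 and KIF2C by 0.69. DNA replication genes (median 0.04, percentile 30.8) and homologous recombination genes (median 0.04, percentile 62.1) did not stand apart. Replication-dependent histones had a median of 0.27 over 39 genes (percentile 99.92) and ribosome biogenesis and MYC targets 0.34 over 44 (percentile 100), with the RNA polymerase I subunit POLR1A at 0.87 and BOP1 at 0.75. YAP and TEAD targets had a median of 0.59 over 25 genes (percentile 100). The kinase NUAK2 was higher by 1.76 and the matricellular CCN1 by 1.02. ANKRD1, dim at 0 h, read 2.31-fold higher.

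Other lists on the high side at 48 h were the metal-binding metallothioneins, with a median of 0.69 over 10 genes (percentile 100), among them MT1B (1.002), MT1F (0.96), MT1L (0.79) and MT1A (0.75). These genes are close paralogs and are not separated here. NF-kB and inflammatory cytokine genes had a median of 0.33 over 30 genes (percentile 100), with the acute-phase gene SAA1 at 1.09, the signalling adaptor TRAF1 at 0.99 and CXCL5 at 0.86. Mesenchymal markers had a median of 0.28 over 19 genes (percentile 98.34), with SPARC at 1.09. The mesenchymal list did not stand apart with normexp, with the mean of all probes or without the filter, where its median was -0.000448. The heat shock list had a median of 0.23 over 27 genes (percentile 97.78), with the co-chaperone BAG3 at 1.36, and did not stand apart after quantile normalisation, with the series table, without the filter or without patches. Cholangiocyte markers had a median of 0.27 over 17 genes (percentile 98.15), a position lost without the filter or without patches. Leukocyte markers had a median of 0.45 over 9 genes (percentile 98.54), a position lost with normexp, with both arrays required or without the filter, where the median was -0.03. CSF1R was the marker with the largest difference (1.12).

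On the low side at 48 h were genes of detoxification. Xenobiotic metabolism genes had a median of -0.42 over 18 genes (percentile 0). The aryl hydrocarbon receptor targets CYP1B1 (-1.77) and CYP1A1 (-1.42), the P450 enzyme CYP4F11 (-1.47) and the aldehyde dehydrogenase ALDH3A1 (-1.42) led it. NRF2 targets had a median of -0.27 over 37 genes (percentile 0), with the aldo-keto reductase AKR1C1 at -2.07, the quinone reductase NQO1 at -0.998, the glutathione synthesis enzyme GCLC at -0.997 and thioredoxin reductase TXNRD1 at -0.86. FOXO and quiescence genes had a median of -0.26 over 21 genes (percentile 0.33), although GADD45B was at 0.97. Autophagy and lysosome genes had a median of -0.13 over 41 (percentile 0.02) and ribosomal proteins of -0.07 over 71 (percentile 0). Ribosomal proteins did not stand apart after quantile normalisation, with the series table or without matching, and their median was 0.04 with normexp. Targets of p53 had a median of -0.12 over 33 genes (percentile 1.5), with GDF15 (-1.52), TP53INP1 (-1.49), TIGAR (-1.42) and TNFRSF10C (-1.28). They did not stand apart after quantile normalisation, with normexp (median 0.02), with the series table or without matching. Ferroptosis and glutathione genes had a median of -0.11 over 24 genes (percentile 1.91), with the iron exporter SLC40A1 at -0.78, and did not stand apart with the mean of all probes or without matching.

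Of 14513 genes compared at 48 h, 447 were higher and 167 lower by at least 2-fold, of which 169 rest on a bound and 130 lie in patches. Of the 12 largest increases, 11 lie in patches, led by GAPLINC (71.6-fold) and SLIT3 (56.4-fold), and the remaining one is RPS10P7 (8.10-fold). Outside patches, GFRA1 was higher by 6.22-fold, the transcriptional coregulator SERTAD4 by 5.94-fold, the growth factor FGF1 by 4.52-fold (against 24 h by 7.81-fold, while another probe gave a log2 change of 0.32) and the small GTPase RAB32 by 4.20-fold. Of the 12 largest decreases, 1 (PRDM13) lies in a patch. The others were DYNC1I1 (4.95-fold), AKR1C8 (4.63-fold), AKR1C1 (4.20-fold, with its other probe at -2.35), the GTPase RRAGD of lysosomal nutrient sensing (4.14-fold), the intermediate filament PRPH (3.94-fold), the pro-apoptotic BMF (3.91-fold), SLC46A3 (3.72-fold), BCAS1 (3.69-fold), the ribonuclease RNASE4 (3.61-fold), the calcium-binding S100P (3.59-fold) and CYP1B1 (3.40-fold, other probe at -1.86). AKR1C genes are close paralogs and are not separated here. The largest values entered as lower bounds were 24.0-fold higher for OTOF, 18.8-fold for PTBP1 and 9.38-fold for PHOSPHO1. These too are ratios to the probe's own undetected signal at 0 h. SLC6A13 was at least 16.2-fold lower, ERVW-1 10.3-fold and PABPC4L 8.42-fold. All of these genes lie in patches. With normexp, 300 genes changed and 90.0% of them were higher, against 72.8% of 614.

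**Figure D3:**
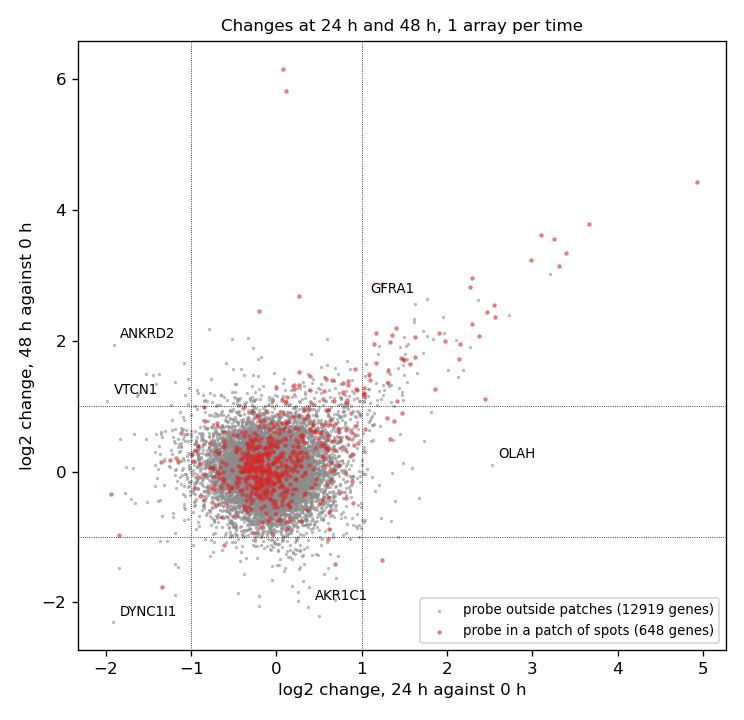
Log2 change of each gene at 24 h (x axis) and at 48 h (y axis) against 0 h, for genes well above background on all 3 arrays. Red points are genes whose probe lies in a patch of spots (648 genes), grey points the other 12919 genes, and dotted lines mark a log2 change of 1 either way. The genes at the upper right, higher at both times, include many red points.

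The third comparison, 48 h against 24 h, does not use the 0 h array. Mitosis genes were higher at 48 h by a median of 1.11 over 65 genes (percentile 100), and 45 of them by at least 1, led by CDC20 (2.07), FAM83D (1.96), KIF20A (1.88) and the kinase AURKA (1.84). YAP and TEAD targets were higher by a median of 1.11 over 25 genes (percentile 100), 16 of them by at least 1, with NUAK2 at 1.94 and CCN2 at 1.92. Also on the high side were ribosome biogenesis and MYC targets (0.64), DNA replication (0.61), mesenchymal markers (0.61), metallothioneins (0.57), histones (0.55) and homologous recombination (0.47). Fibroblast (0.59), endothelial (0.74) and leukocyte markers (0.48) stood on the high side over only 8, 5 and 9 measured genes, and none of these lists stood apart with normexp or without the filter. On the low side were FOXO and quiescence genes (-0.42), NRF2 targets (-0.41), interferon genes (-0.39), xenobiotic metabolism (-0.22), autophagy and lysosome (-0.15), cholesterol synthesis (-0.13), ferroptosis and glutathione (-0.10) and ribosomal proteins (-0.04, and 0.05 with normexp). Metallothioneins did not stand apart without patches, mesenchymal markers without the filter, ferroptosis genes without matching, or xenobiotic genes after quantile normalisation, with the series table or without the filter (median 0.00136). IFI44 was at -1.84, IFIH1 at -1.35, GCLC at -1.66, the sterol enzyme MSMO1 at -1.12 and the cyclin-dependent kinase inhibitor CDKN1A at -1.09.

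Of 14827 genes, 778 were higher and 357 lower at 48 h than at 24 h. Of these, 191 rest on a lower bound and 92 lie in patches. Outside patches the largest increases were ANKRD2 (14.4-fold), VTCN1 (8.38-fold) and the pseudogene SFTA1P (8.16-fold), and the largest decreases AKR1C8 (6.56-fold), BMF (6.28-fold), AKR1C1 (5.44-fold) and the ribosomal RNA RNA5-8SN5 (5.36-fold). GAPLINC, SLIT3 and SPINK1 were also among the largest differences and lie in patches. With normexp, 577 genes changed. The share of higher genes depended on the scaling: it was 68.5% as reported, and 41.2% with scaling to the 75th percentile of probes well above background on all arrays, which moved the median of all genes by -0.19.

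The changes at 24 h and 48 h overlapped in 135 genes higher and 34 lower at both times, among 14217 genes in both comparisons. Independent lists of these sizes would share 5.64 and 2.24. Of the 34, only 8 were well above background on all arrays, and the others rest on a lower bound in at least 1 comparison. A gene well above background only at 0 h can enter both comparisons only as a decrease or as 0. Part of the overlap of lower genes is therefore built in. Both comparisons subtract the same 0 h array. Over the 13567 genes well above background on all arrays, 102 were higher and 8 lower at both times, out of 150 higher and 138 lower at 24 h and 312 higher and 124 lower at 48 h. Unchanged simulated arrays sharing 1 control gave 101 and 99.3 on average, out of longer lists of 377 higher and 375 lower at 24 h and 379 higher and 374 lower at 48 h, so these overlaps cannot be compared directly. Of the 102, 42 lie in patches and 81 differed by under 0.5 between 24 h and 48 h. Outside patches too, a change alike at both times cannot be told from an error of the single 0 h reading. RAB32 (1.76 at 24 h and 2.07 at 48 h), RPS10P7 (3.20 and 3.02) and DYNC1I1 (-1.92 and -2.31) are examples. The shared array cannot be split. Without spots in patches, 78 genes were higher and 18 lower at both times among all genes compared. With all spots kept, the changes at 24 h and 48 h had a Pearson correlation of 0.18 and a Spearman correlation of 0.00 across the 13567 genes. Without spots in patches these were 0.0831 and -0.0197 across 13162 genes. Without the filter on dim probes they were 0.41 and 0.23 across 22371 genes, where probes near background enter. The simulated unchanged arrays had 0.50 and 0.48. The covariance was 0.03, against 0.13 in the simulation, a difference of -0.10. Both values follow from the spreads of the changes, the simulated one from that of 48 h against 24 h alone. Real differences between those arrays raise the simulated value. The gap is therefore no sign that the changes share less than unchanged arrays would. The simulated noise comes from the 24 h and 48 h arrays and need not match the error of the 0 h array. Genes are not independent replicates.

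Several lists stood apart in none of the 3 comparisons. Their medians at 24 h and 48 h against 0 h were -0.12 and 0.14 for apoptosis machinery, -0.04 and 0.03 for chaperones of the unfolded protein response, -0.12 and -0.07 for ABC drug transporters, -0.04 and -0.01 for fatty acid oxidation and PPAR targets, -0.15 and -0.02 for glycolysis and hypoxia, and -0.16 and 0.07 for oxidative phosphorylation. They were -0.12 and 0.15 for the proteasome, -0.11 and -0.05 for antigen presentation, -0.08 and 0.11 for immediate early and serum response genes, -0.14 and -0.01 for TGF-beta targets and -0.24 and 0.05 for Wnt and Notch targets. They were -0.15 and 0.05 for epithelial junctions, -0.14 and 0.09 for extracellular matrix and collagens, -0.21 and 0.16 for matrix proteases, -0.21 and -0.07 for RNA methylation factors and 0.01 and -0.18 for the circadian clock. Delta protocadherins had 3 measured members at each of these times, under the 5 required.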

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

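The tests in this part were chosen after the list results were seen, except that of nuclear RNAs, whose list was fixed before its values were seen.

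Against 0 h, 8 gene lists stood apart on opposite sides of random lists at 24 h and 48 h. With 1 array per time this difference was not tested between cultures. Mitosis and G2/M genes had medians of -0.86 at 24 h and 0.27 at 48 h, replication-dependent histones -0.37 and 0.27, ribosome biogenesis and MYC targets -0.33 and 0.34, YAP and TEAD targets -0.47 and 0.59, and mesenchymal markers -0.36 and 0.28. In the other direction, NRF2 targets had 0.11 and -0.27 and autophagy and lysosome genes 0.07 and -0.13. Ribosomal proteins had -0.0548 and -0.0694, which lie above and below random lists although both medians are below 0, and they stood on opposite sides neither after quantile normalisation nor with the series table nor without matching on expression. Mesenchymal markers did not stand on opposite sides with normexp, with both arrays required, without the filter or with the mean of all probes. Spots in patches do not carry the pattern as a whole, since 8 of the 8 lists still stood on opposite sides without them. List medians could hardly move there. Of genes well above background on all arrays, 648 had their probe in a patch and 12919 did not. An error of the 0 h array enters both changes alike and so cannot by itself make them differ. Where they differ, such an error can still place them on opposite sides of random lists. Without that array, between 48 h and 24 h, mitosis genes differed by 1.11 (random lists 0.05 to 0.32), YAP and TEAD targets by 1.11 (0.02 to 0.43) and NRF2 targets by -0.41 (0.06 to 0.39). The difference between the 2 times thus does not rest on the 0 h array for these lists. All 8 lists stood apart there, a count that choosing them nearly fixes. Whether the 0 h array set the size or the side of either change stays open. Elemene, time in culture, cell density and fresh serum cannot be told apart, because there were 0 vehicle arrays at 24 h or 48 h. A difference in RNA extraction between 24 h and 48 h stays open too. A list fixed as nuclear RNAs was lower at 48 h (percentile 0.77 of random lists), but it also holds transcripts of protein-coding genes. Elemene acting differently at the 2 times stays a biological hypothesis that these arrays cannot test.

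Single genes well above background on all arrays also changed by at least 2-fold in opposite directions at the 2 times, which was likewise not tested. Lower at 24 h and higher at 48 h were ANKRD2 (-1.91 and 1.94), SCGN (-1.09 and 1.66), SFTA1P (-1.53 and 1.498), PTGER4 (-1.38 and 1.49), MMP24 (-1.44 and 1.48), MCAM (-1.04 and 1.41), INHBB (-1.19 and 1.37) and CLK3 (-1.42 and 1.35). The same held for ARHGDIB (-1.03 and 1.28), MATN2 (-1.62 and 1.19), ARID3B (-1.07 and 1.17), RIMS2 (-1.63 and 1.15), VTCN1 (-1.98 and 1.08), CDC20 (-1.04 and 1.04) and MARCHF3 (-1.23 and 1.02). Higher at 24 h and lower at 48 h were SPINK1 (1.24 and -1.35), whose probe lies in a patch, and RNA5-8SN5 (1.42 and -1.004).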

How the results depend on the processing

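Leaving out spots in patches and scaling to the 75th percentile of probes well above background on all arrays were chosen after seeing the data. No paired analysis was possible because each time has 1 array. Counts are given in the order total, higher, lower. With normexp they were 149, 101 and 48 for 24 h against 0 h, 300, 270 and 30 for 48 h against 0 h, and 577, 489 and 88 for 48 h against 24 h, with an overlap of 91, 85 and 6. The higher share was 67.8%, 90.0% and 84.7%, against 54.3%, 72.8% and 68.5%. Without the filter on dim probes they were 1649, 835 and 814, then 1888, 1017 and 871, then 2331, 1308 and 1023, with an overlap of 722, 323 and 399 and correlations of 0.41 (Pearson) and 0.23 (Spearman); probes near background enter there with their own signals. A threshold of log2 2 gave 46, 37 and 9, then 73, 61 and 12, then 73, 50 and 23, with an overlap of 33, 26 and 7. A threshold of 1.5-fold gave 1768, 742 and 1026, then 2218, 1349 and 869, then 3818, 2580 and 1238, with an overlap of 427, 308 and 119. With both arrays required above background the overlap was 110, with 8 lower. Without patches the overlap was 96, 78 and 18, and the changed genes numbered 317, 503 and 1068, of which 309, 479 and 1045 were among those reported. Scaling to the 75th percentile of probes well above background on all arrays gave 117 genes lower at 24 h, and 437 higher and 624 lower at 48 h against 24 h; it moved the median of all genes by 0.12, -0.06 and -0.19 and the higher share to 73.0%, 63.9% and 41.2%. The median of all genes moved by -0.13 at 48 h against 24 h after quantile normalisation and with the series table, and by -0.14 at 48 h against 0 h without the filter. Normexp adds an offset of 50 to every signal, which shrinks log2 changes of dim probes. Median processed signals were 9.88, 13.1 and 14.5 at 0 h, 24 h and 48 h. How much of the lower counts comes from the offset was not tested. Apart from these construction effects the cause was not tested.

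The numbers of lists standing apart (17, 17 and 19) stayed within 1.5 times under every alternative run, and 11, 10 and 12 of these lists kept their side under all 10 alternatives. Of 5569 values of single genes, 5210 stayed on their side of a log2 change of 1, 353 crossed it and 6 reversed: JAG2 at 24 h (-0.43 with normexp), CFLAR at 48 h against 24 h (-0.0521 with the mean of all probes) and, without patches, RPL13A (-0.10) and RPL28 (-0.045) at 24 h and NR4A2 (-0.39 against 0 h, -0.50 against 24 h). Part of this stability was fixed in advance. With both arrays required the values are the main ones, and without the filter only genes dim on an array can move. Scaling to the median or an upper percentile of probes well above background on all arrays shifts all probes of an array alike. Apart from lower bounds, list positions could therefore hardly move there. The series table largely repeats quantile normalisation, with 18, 15 and 21 lists standing apart under each. The 10 alternatives are thus not 10 separate checks of the lists. Between 40.6% and 44.2% of the probes were well above background, so changes of dim transcripts are bounds, are ratios to an undetected signal or were not measured.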

Other observations

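The tests of the patches were chosen after the result was seen, and the list of nuclear RNAs was fixed before its values were seen.

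The nuclear long noncoding RNAs MALAT1 and NEAT1, chosen after their values were seen, differed alike across their probes. All 4 probes of MALAT1 were higher at 24 h than at 0 h, by 0.46 to 1.12, and lower at 48 h, by -0.43 to -1.29. The 3 probes of NEAT1 ranged from 0.25 to 0.89 at 24 h and from -0.71 to -1.49 at 48 h. If nuclear RNA was lost during extraction at 48 h, other RNAs that stay in the nucleus should be lower with them. The list used for this mixes noncoding RNAs with transcripts of protein-coding genes, such as CLK1, DDX17 and SON. It is therefore not a clean set of RNAs that stay in the nucleus. Over its 20 measured members the median change of 48 h against 24 h was -0.17. This lay at percentile 0.77 of random lists, whose central 95% ran from -0.12 to 0.36. Of the 20, 15 lay below the median of all genes, with KCNQ1OT1 at -0.96, RN7SK at -0.87 and FTX at -0.85, while MIAT (1.06) and PVT1 (0.74) were higher. With this mixed list, a difference in extraction may contribute, and a change of these RNAs in the cells stays open, since no test here separates them.

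Large changes clustered on the arrays. In all, 2575 spots lay in patches on some array (1194, 919 and 1457 at 0 h, 24 h and 48 h), against 109 after shuffling spot positions, which argues against chance clustering of changed genes. For changed genes whose probe lies in a patch, 46 other probes outside patches moved by a median of 0.0571 in the direction of the patch probe. For changed genes outside patches, 112 other probes moved by 0.563. Local damage or debris on the array surface is therefore a likely cause of the changes seen in patches, and the increases of RHBDL1, GSDMD, GAPLINC and SLIT3 carry that doubt. RHBDL1 and GSDMD differed by only 0.13 and -0.05 between 48 h and 24 h, so their increases rest on the 0 h reading. GAPLINC and SLIT3 differed by 0.07 and 0.11 between 24 h and 0 h, so theirs rest on the 48 h reading.

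The signal of the E1A spike-in RNA was higher than at 0 h by 0.20 at 24 h and 0.17 at 48 h on the log2 scale, while the 75th percentile of all probes was higher by 0.22 and 0.50. The scaling removes the shift of the 75th percentile and does not use the spike-in. Higher and lower are therefore relative to the other probes of an array. Measured against the spike-in, all changes at 48 h would lie further up, and small decreases need not remain decreases. The 0 h array had a median SD over 10 spots of 0.0913, against 0.0468 at 24 h and 0.0426 at 48 h.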
